A study of Mus musculus with 2 samples.

How the data were processed

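Acetylation of lysine 9 of histone H3 (H3K9ac), a mark found at active promoters, was profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse midbrain at embryonic day 16.5. Per the labels, the tissue was pooled from male and female embryos of strain B6NCrl. The 2 libraries are given there as biological replicates 1 and 2 of a single group, and replicate 2 was made from 37 embryos. An input control experiment is named in the labels and was not analysed here.

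The deposited data used here were 4 peak lists. Per the file headers, there was a list for each replicate, a list called on both replicates together (the pooled list) and a list of replicated peaks derived from the pooled list and both replicates' lists. Per the file headers, the replicate and pooled lists were derived from filtered alignments to the mm10 assembly, which is GRCm38, together with 2 further files that were not used here. The aligner, the peak caller and the rule by which a peak counted as replicated are not given in the sources used here. Each deposited peak carried an enrichment value by the authors, a signal whose scale is not given in the sources used here. Each also carried a −log10 p-value and a −log10 q-value by the authors. The enrichment is the authors' own value, and values were compared only within a list. It was used to describe, rank and filter peaks, to place the medians of gene lists among random lists and to compare X-linked with autosomal genes. The lists hold no read counts, so the depth of the libraries is unknown. Precision is therefore given as exact Clopper-Pearson 95% binomial intervals over peaks or genes, which cover counting error only.

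The GENCODE M21 annotation and the GRCm38 sequence were used for genes and positions. No peak or gene lay past the end of its chromosome, which was checked for 21 chromosomes. Coordinates are 1-based. Analyses of genes and positions used chromosomes 1 to 19, X and Y. The promoter of a gene was the region within 1 kb of any of its annotated transcription starts, and 21911 protein-coding genes with a unique name were tested. Peaks outside promoters were assigned to exons, then introns, then intergenic sequence. A distal peak lay more than 5 kb from every annotated start of any gene class. A gene was called CpG-rich where the 500 bp on each side of a start had a GC share of at least 0.5 and an observed to expected CpG ratio of at least 0.6, using the start with the highest ratio.

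Overlaps were computed with bedtools 2.31.1. A peak counted as overlapped where at least 50% of either peak's length was shared. Chance levels came from 100 random placements of the peaks on their own chromosomes outside assembly gaps of 100 bp or more. Shares were compared by two-sided Fisher's exact tests with scipy 1.17.1, and the p-values of the 27 gene lists were adjusted by the Benjamini-Hochberg method. A p-value too small to be represented is given as at most 1e-300. The position of a list's median enrichment, with genes without a peak at 0, was described as its percentile among 10000 random lists of the same size. Genes and peaks are not replicates, and these tests describe the libraries studied, not a population of animals. With 1 group there was no contrast between conditions to test.

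The gene lists, the tests and the rule for naming genes were set before the data were examined. Of the listed symbols, 408 matched a gene outside the olfactory receptors, 1 of them through a synonym, and 1 symbol, Ahsp, had no match. The text names the 15 genes with the promoter peaks of highest enrichment, the 15 with the widest promoter peaks and the 5 distal peaks of highest enrichment. For each list it names the 4 members of highest enrichment and up to 4 without a peak, or up to 6 members with a peak where most have none. All members of the midbrain dopaminergic list and of the Hox list were looked at. Names outside this rule were chosen after their values were seen, and this is stated where they appear.

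The overlap, distance and list steps were tested on simulated data. Among 73501 simulated peaks, 59.87% were given a partner, and 100% of these were found, with 2.68% of the others found by chance. All 500 distances tested equalled those of a direct search. Of 200 simulated lists of 15 genes among 21911, with a peak share equal to that of the background (65%), 3% passed an unadjusted p of 0.05. With a simulated share of 95% the test called 86.5% of lists, and with 10% it called 100%.

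The alternatives tried were overlap by 1 bp or by 50% of both peaks, a −log10 q-value of at least 5, the strongest 20000 peaks of each list, and ranking by p-value. Promoter windows of 500 bp and 2 kb, starts of all annotated genes, the 5' end of each gene only, and distal limits of 2 kb and 10 kb were also tried. So were the pooled list, each replicate's list alone and a background without the Olfr, Vmn and numbered Gm genes. Chosen after seeing the data were the use of only those replicated peaks overlapped in both replicates' lists and of random lists matched on CpG class. The ratio of enrichment between X and autosomes, with its bootstrap of 1000 draws and its 100000 permutations, was also added then.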

Results

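The data describe where H3K9ac lay in the genome of the embryonic mouse midbrain at day 16.5, in 2 libraries from pooled embryos. Replicate 1 had 73509 peaks covering 42.2 Mb (median width 302 bp) and replicate 2 had 69702 peaks covering 35.8 Mb (median width 265 bp). The pooled list held 63985 peaks. The replicated list held 42129 peaks covering 35.5 Mb, with a median width of 551 bp and a median of the authors' enrichment of 4.92 (range 1.79 to 46.1). All 42129 replicated peaks were present with identical borders in the pooled list. A −log10 q-value of at least 5 was reached by 62.7% of replicated peaks.

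The first comparison asked how far the replicates shared their peaks. Strong H3K9ac sites were found in both libraries, while most weak sites were listed in 1 library. In the strongest 10% of replicate 1, 100% of 7350 peaks were overlapped by replicate 2 (95% interval 99.95% to 100%), against 13.9% of the weakest 10% (13.1% to 14.7%). For replicate 2 the shares were 99.99% (99.92% to 100%) and 26.1% (25.1% to 27.2%). Over the whole lists, 48.2% of replicate 1 peaks were overlapped in replicate 2 (47.8% to 48.6%), against 2.37% ± 0.059 (SD over 100 random placements). Of replicate 2 peaks, 56.9% were overlapped in replicate 1 (56.5% to 57.3%), against 2.499% ± 0.067 (SD over 100 random placements). No random placement came above 2.653%. At the level of genes the libraries were closer: 14219 genes had a promoter peak in both, 434 in replicate 1 only and 292 in replicate 2 only. The genes in both made up 97.0% of the replicate 1 genes and 98.0% of the replicate 2 genes.

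**Figure D1:**
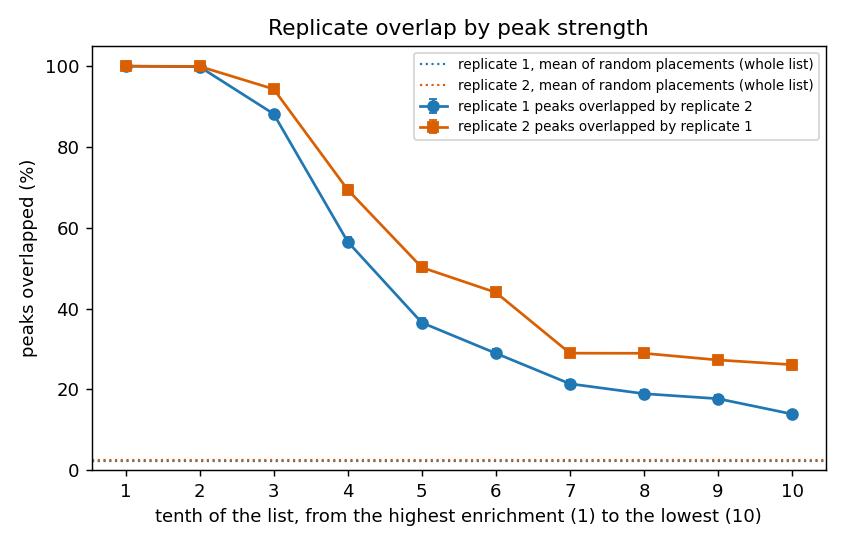
The share of each replicate's peaks (%) overlapped by the other replicate is plotted for each 10% of the list, from the highest enrichment to the lowest, with exact 95% intervals as bars and the means of 100 random placements of the whole list as dotted lines. The share falls from 100% to 13.9% in replicate 1 and from 99.99% to 26.1% in replicate 2.

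The second comparison asked where the replicated peaks lay. H3K9ac was concentrated at promoters of protein-coding genes, which held 20501 peaks, or 48.7% (95% interval 48.2% to 49.1%), 8.85 times the 5.50% ± 0.108 (SD) of the random placements. Exons held 5.71%, introns 23.4% and intergenic sequence 22.3% of peaks, against 6.33%, 31.3% and 56.9% by random placement. Promoters were assigned first, so their excess lowers the other shares, which by themselves do not show depletion. Promoter peaks had a median enrichment of 11.2 and a median width of 1022 bp, and intergenic peaks 4.07 and 400 bp. The promoter share was 97.2% in the strongest 10% of the list and 18.8% in the weakest. Pooled peaks that were not in the replicated list lay at promoters less often, with 3290 of 21856 peaks or 15.1% (median width 202 bp; odds ratio 5.35, 95% interval 5.13 to 5.58, two-sided Fisher's exact test, p of at most 1e-300). These peaks were also weaker, with a median enrichment of 2.97 against 4.92 for replicated peaks. Peaks were not matched on strength, so the odds ratio cannot separate replication from strength. The promoter share lay above every random placement in each replicate's own list too, at 33.2% in replicate 1 and 38.1% in replicate 2.

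Summits lay downstream of transcription starts. Among 1686 genes with 1 annotated start and a peak, 79.5% had the summit of their strongest promoter peak downstream. Over all 1686 genes the median position was 203.5 bp downstream (quartiles 71.3 and 384 bp).

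**Figure D2:**
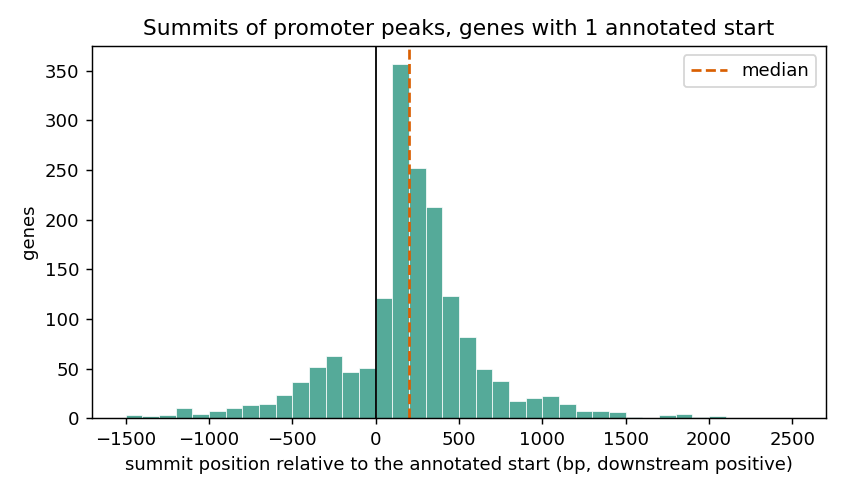
The histogram gives the number of genes by the position of the promoter peak summit relative to the annotated start (bp, downstream positive) in steps of 100 bp, for 1686 genes with 1 annotated start. The dashed line marks the median of 203.5 bp over all these genes, and 79.5% of summits lie downstream.

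The third comparison asked which genes carried the mark. Of 21911 protein-coding genes, 14250 (65.04%) had a replicated promoter peak. Nearly all CpG-rich genes did, 10891 of 11135 or 97.8%, against 3359 of 10776 other genes or 31.2%. Median enrichment among genes with a peak was 18.0 in the CpG-rich class and 9.95 in the other.

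The highest enrichment was at Srsf6, which encodes a splicing factor (46.1, chromosome 2, 162930526 to 162932850, over the first part of the gene). It was followed by Marcksl1, a regulator of the actin cytoskeleton (44.6), Actb, cytoplasmic beta-actin (43.9), and Fnbp1l (42.7). A peak of 42.3 on chromosome 15, from 98951552 to 98953540, lay over the first part of Tuba1a, the main alpha-tubulin of developing neurons, and was shared with the overlapping gene Gm49450. Ncam1, a neural cell adhesion molecule, had 40.8, Basp1, a growth cone protein, 40.3, and Tmsb10, an actin-binding thymosin, 40.3. The others were Rbm39 (41.4), Sp3 (41.3), Kmt5b (40.6), Sbk1 (39.99) and a peak of 41.4 shared by Hipk2 and Tbxas1. All 15 genes had a promoter peak in each replicate's own list.

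The widest promoter peaks were mostly at other genes. The widest spanned 8976 bp on chromosome 9, from 58195879 to 58204854, over Islr2, a neuronal membrane protein, and its neighbour Islr, with an enrichment of 7.69. Peaks of 8759 bp lay at an internal start of the transcription factor gene Zfhx3, 8459 bp at Mn1, 8232 bp at the protocadherin gene Pcdh7 and 8132 bp at Mex3a. Gad1, which encodes the enzyme that makes the transmitter GABA, had a peak of 7823 bp on chromosome 2 from 70561271 to 70569093. Bcl11a, a transcription factor of developing neurons, shared a peak of 7487 bp with A830031A19Rik. Mdga1 had 7296 bp, the neuronal factor Myt1l 7272 bp, Tnrc18 7091 bp, Sbk1 7089 bp, the neuronal repressor Scrt1 7029 bp and Rhof 6989 bp. The Gad1, Mdga1 and Myt1l peaks lay near internal starts and not at the genes' 5' ends. The Rhof peak lay wholly upstream of the gene, with only its border within 1 kb of the start. The median over genes with a promoter peak was 1414 bp (quartiles 981 and 1990 bp). Only Sbk1 was in both top groups.

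The fourth comparison set 27 gene lists against the other protein-coding genes. Most neuronal and progenitor genes had a promoter peak. All 22 pan-neuronal genes had a promoter peak (two-sided Fisher's exact test against all other protein-coding genes, adjusted p = 0.00075), led by Ncam1, the neuronal tubulin Tubb3 (34.8) and the RNA-binding factors Celf4 (30.4) and Elavl3 (30.0). Of 17 synaptic maturation genes, 16 had one (Fisher's exact test, adjusted p = 0.0175), led by the receptor gene Gabra2 (25.8), the postsynaptic scaffold Shank1 (23.8), Homer1 (22.2) and Gabrb3 (21.1). The neuropeptide gene Vip had none, and the synaptic call was lost with a background without olfactory, vomeronasal and numbered predicted genes (Fisher's exact test, adjusted p = 0.145). All 16 genes of radial glia and neural progenitors had a peak (Fisher's exact test, adjusted p = 0.00367), with 33.9 at Msi1, 21.4 at Hes5, shared with Pank4, 19.3 at Prom1 and 17.6 at Sox2. All 18 cell cycle genes had one (Fisher's exact test, adjusted p = 0.00266), with 22.2 at Aurka, shared with Cstf1, 17.7 at Rrm2, 16.0 at Mcm4, shared with Prkdc, and 14.0 at Ccne1. In random lists matched on CpG class, chosen after seeing the data, 81.2% and 94.1% of genes were expected to have a peak, and the count of each list, the highest possible, did not pass (permutation, adjusted p = 0.0571 and 0.673). The median enrichment of the pan-neuronal list (18.5) lay at the 99.5th percentile of random lists and that of the synaptic list (16.8) at the 95.2nd. The medians of the progenitor list (9.60) and of the cell cycle list (8.18) lay at the 46.1st and 35.5th percentile. These percentiles also reflect the share with a peak, since genes without one counted as 0. Over all genes with a promoter peak the median was 16.2, and over the CpG-rich ones 18.0.

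**Figure D3:**
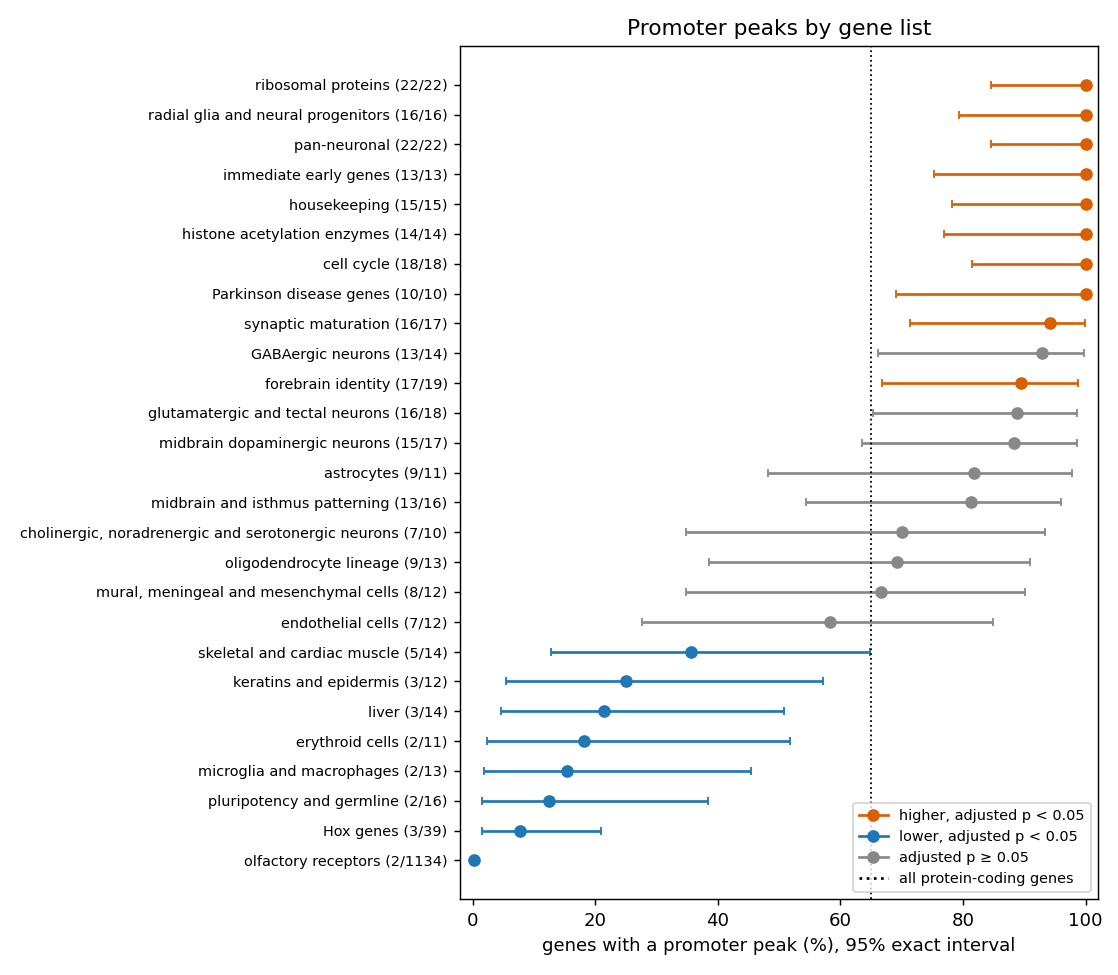
For each of 27 gene lists the point gives the share of genes (%) with a replicated promoter peak, with its exact 95% interval, the counts follow the name, and the dotted line is the 65.04% of all protein-coding genes. Orange lists were higher and blue lists lower at an adjusted p under 0.05, and grey lists passed neither way.

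Transmitter and midbrain lists had mostly marked genes without passing the test. Of 17 midbrain dopaminergic genes, 15 had a promoter peak (88.2%, 95% interval 63.6% to 98.5%, Fisher's exact test, adjusted p = 0.0911). The midbrain transcription factor genes had peaks of 14.8 at En2, 14.8 at En1, 12.9 at Otx2, 12.3 at Nr4a2 and 12.0 at Pitx3. The other regulators had 7.87 at Lmx1a, 4.28 at Foxa1, 4.27 at Lmx1b and 3.86 at Foxa2. The receptor gene Ret had 14.4, and Drd2, a dopamine receptor, 5.70. Among genes of dopamine synthesis and transport, Gch1 had 12.7, Slc18a2 8.99, Ddc 4.38 and the dopamine transporter gene Slc6a3 3.81. The Ddc and Foxa2 peaks lay near internal starts, with none at the gene's 5' end, and the strongest Pitx3 peak lay at a start near its 3' end. Th, the rate-limiting enzyme of dopamine synthesis, had no replicated peak and was marked in replicate 2 only, and Aldh1a1 had none in either library. The list passed the test with a 2 kb window (Fisher's exact test, adjusted p = 0.032) and in replicate 2 alone (Fisher's exact test, adjusted p = 0.0251). It did not with a −log10 q-value of at least 5, where 70.6% of its genes had a peak (Fisher's exact test, adjusted p = 0.67). Nor did it with a 500 bp window (Fisher's exact test, adjusted p = 0.185), a background without olfactory, vomeronasal and numbered predicted genes (0.346) or random lists matched on CpG class (0.617 by permutation).

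Of 16 midbrain and isthmus patterning genes, 13 had a peak (Fisher's exact test, adjusted p = 0.247), led by En2, En1, Otx2 and Meis2 (12.5), while Pax2 (marked in replicate 2 only), Dmbx1 (replicate 1 only) and Wnt1 had no replicated peak. Of 14 GABAergic genes, 13 did (Fisher's exact test, adjusted p = 0.0604), led by Zfpm2 (18.0), Zfpm1 (16.5), Lhx5 (14.8) and Ascl1 (14.6), with no replicated peak at Helt, which had one in replicate 2 and the pooled list. Of 18 glutamatergic and tectal genes, 16 did (Fisher's exact test, adjusted p = 0.0604), with 22.7 at Tcf7l2, 16.4 at the glutamate transporter gene Slc17a6, 15.7 at Ebf1 and 13.1 at Ebf3. Slc17a8 had a peak in replicate 1 only. Neurod6 had one in both replicates' own lists and in the pooled list but no replicated one. The GABAergic list passed in replicate 2 alone (Fisher's exact test, adjusted p = 0.00766), and the glutamatergic list passed in each replicate alone (Fisher's exact test, adjusted p = 0.00508 and 0.0167). Neither passed with the background without olfactory, vomeronasal and numbered predicted genes (Fisher's exact test, adjusted p = 0.201 and 0.254) or against random lists matched on CpG class (permutation, adjusted p = 1 and 0.171). Of 10 cholinergic, noradrenergic and serotonergic genes, 7 had a peak (Fisher's exact test, adjusted p = 1). Slc5a7 had 11.9, Chat and Slc18a3 shared a peak of 5.70 and Slc6a4 had 5.34. Tph2, Dbh and Phox2b had none.

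Forebrain identity genes were marked in 17 of 19 cases (Fisher's exact test, adjusted p = 0.0425), but mostly weakly. The list's median enrichment was 4.73, at the 15.7th percentile of random lists, so its share and its median pointed opposite ways. Weak marking did not set it apart from the midbrain and isthmus patterning list, whose median was 4.72, at the 17.0th percentile. The dopaminergic list had a median of 7.87, at the 33.6th. The cortical regulators Lhx2 (24.3) and Bcl11b (22.8) led the forebrain list, then Emx2 (9.05) and Satb2 (9.003). Tbr1 and Rax had a peak in replicate 2 but no replicated one. By Fisher's exact test the call was lost with a −log10 q-value of at least 5 (adjusted p = 0.844), a 500 bp window (0.302), replicate 1 alone (0.168), peaks overlapped in both replicates (0.125) and the background without olfactory, vomeronasal and numbered predicted genes (0.254). Against random lists matched on CpG class the direction turned, with 89.5% observed and 90.9% expected (permutation, adjusted p = 1).

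Glial and vascular lists did not differ from other genes by the test. Astrocyte genes had a peak in 9 of 11 cases (Fisher's exact test, adjusted p = 0.409), with 23.3 at Glul, shared with Teddm2, 19.7 at Slc1a2, 16.4 at Nfia, shared with E130114P18Rik, and 14.8 at Nfib. The mature markers Gfap and S100b had no replicated peak, and with a −log10 q-value of at least 5 the list's share was 45.5%. Oligodendrocyte lineage genes had one in 9 of 13 cases (Fisher's exact test, adjusted p = 1), with 16.8 at Mbp, 8.08 at Cnp, 7.45 at Olig1 and 6.26 at Nkx2-2. The myelin genes Plp1, Mog, Mag and Mobp had none. Endothelial genes had one in 7 of 12 cases (Fisher's exact test, adjusted p = 0.859), led by Egfl7 (14.5, shared with Gm20532), Kdr (12.1), Erg (6.54) and Esam (6.54). Cdh5, Tek, Tie1 and Slco1c1 had no replicated peak. Mural, meningeal and mesenchymal genes had one in 8 of 12 cases (Fisher's exact test, adjusted p = 1), led by Prrx1 (8.46), Twist1 (7.66), Foxc1 (6.52) and Pdgfrb (5.60). Foxc2, Col3a1, Dcn and Lum had no replicated peak.

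General lists were marked throughout. All 22 ribosomal protein genes had a peak (Fisher's exact test, adjusted p = 0.00075), led by Rps6 (35.5), Rps8 (32.1), Rps19 (29.7) and Rpl8 (28.3). All 15 housekeeping genes did (Fisher's exact test, adjusted p = 0.00501), led by Actb, Ubc (35.5, shared with Gm10382), Eef1a1 (33.4) and Ppia (31.2). All 13 immediate early genes did (Fisher's exact test, adjusted p = 0.012), led by Dusp1 (25.5), Nr4a1 (21.4), Jun (19.3) and Npas4 (13.9). All 14 histone acetylation enzyme genes did (Fisher's exact test, adjusted p = 0.00789), led by Ep300 (32.8), Hdac2 (30.9), Kat6b (28.7) and Crebbp (28.3). All 10 Parkinson disease genes did (Fisher's exact test, adjusted p = 0.0309), led by Atp13a2 (28.2), Pink1 (22.8), Uchl1 (21.5) and Park7 (20.3, shared with Tnfrsf9). The Parkinson disease call was lost in replicate 1 alone (Fisher's exact test, adjusted p = 0.0552). With a background without olfactory, vomeronasal and numbered predicted genes, the immediate early, histone acetylation and Parkinson disease calls were lost (Fisher's exact test, adjusted p = 0.0502, 0.0502 and 0.123). None of these 5 lists, all at their highest possible count, passed against random lists matched on CpG class (permutation, adjusted p = 0.673, 0.361, 0.714, 0.0571 and 0.178 in the order given).

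Most genes of microglia, blood and other tissues had no replicated promoter peak. Microglial and macrophage genes had a peak in 2 of 13 cases (Fisher's exact test, adjusted p = 0.00154), the lysosomal gene Hexb (15.9) and Aif1 (2.97). Erythroid genes had one in 2 of 11 cases, Gypa (5.25) and Klf1 (4.59) (Fisher's exact test, adjusted p = 0.00501). Liver genes had one in 3 of 14 cases, Trf (4.07, shared with Gm20425), Afp (3.78) and Apoa1 (2.89) (Fisher's exact test, adjusted p = 0.00367). Muscle genes had one in 5 of 14 cases (Fisher's exact test, adjusted p = 0.0422). The strongest of these, at Mylpf (21.2), was shared with Tbc1d10b, and the 6.89 at Ckm was shared with Klc3. Des had 4.80, Myod1 3.95 and Myh7 3.57. The muscle call was lost with a 2 kb window (Fisher's exact test, adjusted p = 0.333) and with a 500 bp window (Fisher's exact test, adjusted p = 0.0647). It was also lost with only peaks overlapped in both replicates (Fisher's exact test, adjusted p = 0.065). Keratin and epidermal genes had one in 3 of 12 cases, Lor (23.5), Krt10 (13.4) and Krt1 (11.8) (Fisher's exact test, adjusted p = 0.0115). The only promoter peaks of Krt1, Afp and Aif1, and the strongest of Krt10, lay near the genes' 3' ends, away from their 5' ends. Pluripotency and germline genes had one in 2 of 16 cases, Dazl (10.8) and Esrrb (5.65) (Fisher's exact test, adjusted p = 0.000199). Against random lists matched on CpG class, chosen after seeing the data, the microglial, liver, muscle and keratin calls were lost (permutation, adjusted p = 0.361, 0.76, 0.728 and 0.728), and the erythroid list (adjusted p = 0.728, permutation) could not have passed as lower. With a −log10 q-value of at least 5 the microglial, liver and muscle calls held, with 7.69%, 0% and 21.4% of genes marked. In replicate 1 alone the microglial count was 4 and the liver count 5, and both calls held (Fisher's exact test, adjusted p = 0.0286 and 0.0341). Olfactory receptor genes had one in 2 of 1134 cases, Olfr94 (18.0) and Olfr658 (4.07) (Fisher's exact test, adjusted p of at most 2.7e-299).

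The Hox genes, which set position along the trunk and hindbrain, were nearly free of the mark. Of 39 genes, 3 had a promoter peak, or 7.69% (95% interval 1.62% to 20.9%, Fisher's exact test, adjusted p = 1.26e-12). They were Hoxa7 (7.25, chromosome 6, 52221349 to 52221785), Hoxa1 (4.91, chromosome 6, 52158126 to 52158720) and Hoxd1 (3.15, chromosome 2, 74762709 to 74763355). Hoxd1 had a peak in replicate 1 and not in replicate 2. The other 36 Hox genes had no replicated peak, although 29 of the 39 were CpG-rich, and Hoxc6 had a peak in replicate 1 and the pooled list. The Hoxb cluster, from 96194316 to 96368256 on chromosome 11, held no peak in any of the 4 lists. Hox genes lie side by side in clusters, while the interval and the test treat them as independent, so both may overstate the precision.

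**Figure D4:**
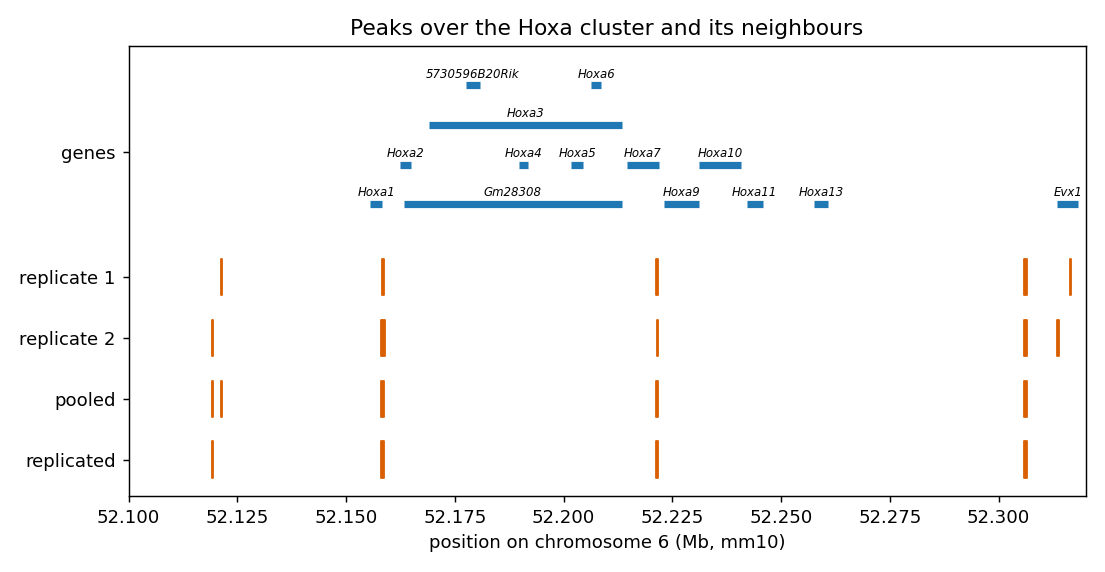
Peaks of the 4 lists (orange) are drawn to scale, with a minimum line width, over protein-coding genes (blue) of the Hoxa cluster and its neighbours on chromosome 6 (Mb, mm10). Inside the cluster the replicated list has 2 peaks, at Hoxa1 and Hoxa7.

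Promoter CpG content differed between the lists. Against random lists matched on CpG class, chosen after seeing the data, 2 lists were higher, the pan-neuronal (random lists matched on CpG class, adjusted p = 0.0027) and the synaptic list (adjusted p = 0.0173 by the same permutation). Against the same random lists 3 lists were lower, namely Hox, pluripotency and germline, and olfactory receptors (each adjusted p = 0.0018 by permutation, the smallest these draws can give). The draws came from all other genes of each class, and none of the 1134 olfactory receptor genes was CpG-rich. Only 2 of them had a peak, which lowered the share expected of other lists' members outside the CpG-rich class. The match was not combined with the background without olfactory, vomeronasal and numbered predicted genes. That background by itself ended the synaptic call (Fisher's exact test, adjusted p = 0.145). For some lists the match on CpG class left only 1 direction open. A higher call was out of reach where the expected share was near its ceiling or, for Parkinson disease genes (77.8% expected), where the list held only 10 genes. With a peak at each member, the smallest unadjusted p was 0.468 for GABAergic neurons, 0.427 for cell cycle, 0.133 for forebrain identity, 0.391 for ribosomal proteins, 0.145 for housekeeping, 0.478 for immediate early genes and 0.0517 for Parkinson disease genes. For radial glia and for histone acetylation enzymes, also at their highest count, it was 0.0144 and 0.0151 (adjusted p = 0.0571 for both, by permutation). For midbrain and isthmus patterning, a peak at each of the 16 genes would have given an unadjusted 0.0454, which adjustment would not have kept. For erythroid cells a lower call was out of reach, since no peak at all would have given 0.0327, which adjustment would not have kept. With a background without olfactory, vomeronasal and numbered predicted genes, 5 lists were higher in place of 10, and 8 were lower.

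The fifth comparison described H3K9ac away from transcription starts. Distal peaks numbered 11820 (28.1%), with a median enrichment of 3.83 and a median width of 362 bp, and 50.5% of them lay inside gene bodies. The 5 of highest enrichment were intergenic in the annotation used. The strongest (32.6, chromosome 17, 88255866 to 88257569) lay 183142 bp from the start of Foxn2. The next were on chromosome 1 from 165280652 to 165284530 (27.7, 11259 bp from Gpr161) and on chromosome 9 from 77909416 to 77911653 (27.5, 5711 bp from Elovl5). The others were on chromosome 10 from 59969671 to 59970966 (26.3, 17837 bp from Ddit4) and on chromosome 1 from 86441074 to 86443865 (25.9, 14745 bp from Tex44). In the RefSeq annotation of the same assembly, genes lay within 1 kb of 3 of these peaks, the lncRNA genes Gm31615 on chromosome 17 and Gm32700 near Tex44, and Tiprl and Gpr161 themselves. The number of distal peaks was 4559 with a −log10 q-value of at least 5, and it was 29691 in replicate 1's own list and 23604 in replicate 2's.

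The last comparison set the X chromosome against the autosomes, since both pools held male and female embryos. X-linked genes were marked less often and more weakly. Of 948 X-linked genes 463 had a promoter peak, or 48.8% (95% interval 45.6% to 52.07%), against 13784 of 20780 autosomal genes or 66.3% (odds ratio 0.485, two-sided Fisher's exact test, p = 3.35e-27). Much of this gap went with CpG content, since autosomal shares in each CpG class would give 50.6% on X. Among CpG-rich genes the shares were 95.6% and 97.9% (Fisher's exact test, p = 0.018), and among the others 30.2% and 31.8% (Fisher's exact test, p = 0.42). Peak density was 5.44 per Mb on X and 16.7 per Mb on the autosomes. Among genes with a peak, median enrichment was 10.4 on X and 16.5 on the autosomes, a ratio of 0.63 (95% bootstrap interval 0.604 to 0.658; permutation test over genes, two-sided, p = 1e-05, the smallest 100000 permutations can give). The ratio was 0.662 in replicate 1 and 0.627 in replicate 2. The Y chromosome held 3 replicated peaks, at Kdm5d (5.34), Uty (5.12) and Ddx3y (4.49), which were named after their values were seen.

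**Figure D5:**
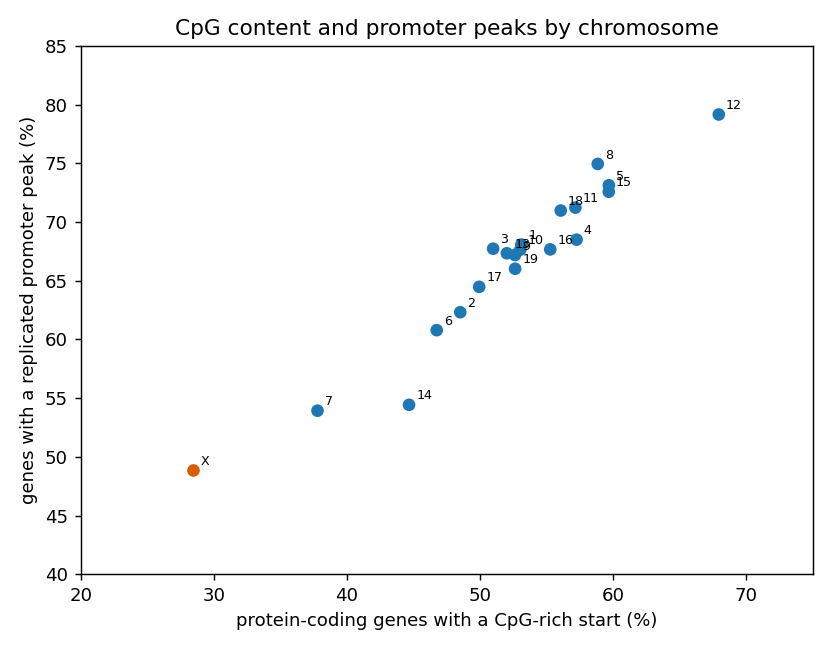
Each point is an autosome or the X chromosome, with the share of its protein-coding genes that are CpG-rich (%) against the share with a replicated promoter peak (%); the Y chromosome is left out, and the axes do not start at 0. The X chromosome (orange) has the lowest values of those plotted, 28.5% and 48.8%, and chromosome 12 the highest, 68.0% and 79.2%.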

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

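The comparisons of the report did not address lincRNA genes, scaffolds or the single replicates' peaks outside the pooled list. The input control was not analysed here, and no chance level is given for these counts.

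Among 5854 lincRNA genes, 562 (9.6%) had a replicated peak at a start more than 5 kb from every protein-coding start. The names given here were chosen after their values were seen. Host genes of the neuronal microRNA miR-124 led: Mir124a-1hg had an enrichment of 35.2 with a peak of 11296 bp on chromosome 14 from 64584968 to 64596263, the widest in the replicated list, and Mir124-2hg had 32.9 with a peak of 4634 bp. C130071C03Rik followed with 30.7, at a peak shared with Gm26803, and Miat and Rmst, long RNAs studied in neurons, had 27.8 and 25.5.

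A further 10 replicated peaks lay on unplaced or unlocalized scaffolds. No pooled peak overlapped 20666 replicate 1 peaks (28.1%) and 17823 replicate 2 peaks (25.6%).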

How the results depend on the processing

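The peak overlap between replicates, the promoter share, the count of genes with a promoter peak, the excess of promoters in replicated over other pooled peaks, the lower share of X-linked genes and the ratio of X to autosomal enrichment kept their direction and side of the threshold, or stayed within 1.5 times, under each alternative run on them. Overlap ranged from 36.8% to 84.6% for replicate 1 and from 38.8% to 91.5% for replicate 2. The promoter share ranged from 33.2% to 66.1%. Ranking by p-value moved the share overlapped in the weakest 10% to 12.7% in replicate 1 and 21.7% in replicate 2. Depth is unknown, so its limits on weak peaks cannot be stated.

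Values for lists are adjusted p-values, and the cause of each change was not tested except where the background itself changed. Leaving out the olfactory, vomeronasal and numbered predicted genes left 5 lists higher and ended the call for synaptic maturation (0.145), forebrain identity (0.254), immediate early genes (0.0502), histone acetylation enzymes (0.0502) and Parkinson disease genes (0.123). Random lists matched on CpG class, chosen after seeing the data and drawn with the olfactory receptors in the pool, left 2 lists higher and 3 lower. They ended the call for radial glia and neural progenitors (0.0571), cell cycle (0.673), microglia (0.361), erythroid cells (0.728), liver (0.76), muscle (0.728), keratins (0.728), ribosomal proteins (0.673), housekeeping (0.361), immediate early genes (0.714), histone acetylation enzymes (0.0571) and Parkinson disease genes (0.178), and turned the sign for forebrain identity (1). Of these, the lists of radial glia and neural progenitors, cell cycle, ribosomal proteins, housekeeping, immediate early genes, histone acetylation enzymes and Parkinson disease genes were at their highest possible count, and forebrain identity could not have passed as higher nor erythroid cells as lower at any count, so these changes follow from the comparison itself. A 500 bp window ended the call for forebrain identity (0.302) and muscle (0.0647) and gave one for GABAergic neurons (0.0404). A 2 kb window ended that for muscle (0.333) and gave one for dopaminergic neurons (0.032). A −log10 q-value of at least 5 ended that for forebrain identity (0.844), gave calls for GABAergic (0.0354) and glutamatergic neurons (0.0366) and left 4559 distal peaks. Only peaks overlapped in both replicates, also chosen after seeing the data, ended the call for forebrain identity (0.125) and muscle (0.065) and gave calls for GABAergic (0.0401) and glutamatergic neurons (0.042). Leaving out each replicate in turn gave 0.0251 to 0.0969 for dopaminergic, 0.00766 to 0.064 for GABAergic and 0.00508 to 0.0167 for glutamatergic neurons, 0.00283 to 0.168 for forebrain identity, 0.0269 to 0.0552 for Parkinson disease genes and 23604 to 29691 distal peaks. Single genes were followed for all list members outside the olfactory receptors and for the genes of highest enrichment and widest peaks. Of these, 30 lost their promoter peak with the stricter q-value and 401 did not change. When only the 5' end of the gene was used, 34 lost it and 397 did not change. No paired analysis was possible because there was 1 group.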

Other observations

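Distal peaks were unevenly spread over genes. The names in this paragraph were chosen after their values were seen. By nearest protein-coding gene, Gse1 had 54 distal peaks, Zfhx3 51, Zmiz1 38, Zfp423 37 and Rapgef5 36, and the neuronal genes Myt1l, Celf4 and Rbfox3 had 32, 31 and 29. The mean over all protein-coding genes was 0.54 distal peaks per gene. It was 4.56 for the glutamatergic and tectal list, 4.06 for the midbrain and isthmus patterning list, 3.82 for the pan-neuronal list, 2.86 for the GABAergic list, 2.75 for radial glia and neural progenitors, 2.21 for forebrain identity, 1.94 for the dopaminergic list, 1.82 for astrocytes and 1.62 for immediate early genes. It was 0.769 for microglia, 0.529 for synaptic maturation and 0.3 for the cholinergic, noradrenergic and serotonergic list. The medians were lower, at 2, 3, 1, 2, 1.5, 1, 0, 0, 1, 0, 0 and 0 in the same order, and Celf4 and Rbfox3 held most of the 84 pan-neuronal distal peaks. It was 0.051 for the Hox list. Gene length and spacing were not controlled for.

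Of the CpG-rich genes, 244 had no replicated promoter peak, and 26 of these (10.7%) were Hox genes.

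The tests on the CpG content of Hox genes, on both explanations for peaks without overlap in both lists and on the escape genes against CpG-rich X-linked genes were chosen only after the result was seen.

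Hox promoters lacked peaks although most were CpG-rich. In random lists matched on CpG class a mean of 31.6 of 39 genes had a peak and the lowest count was 26, against 3 Hox genes, which argues against low CpG content as the cause. The Hox promoters are also not repeated sequence: the median Hox gene had 99.5% of its 32-base sequences within 1 kb of the start occurring once on the chromosomes (lowest gene 93.1%), against 99.3% for 400 CpG-rich genes with a peak. The replicated list had 4 peaks inside the Hox clusters. A hypothesis left open is that these genes are silent in midbrain cells, which peak lists of 1 tissue and 1 mark cannot test.

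X-linked promoter peaks were fewer and weaker than autosomal ones. CpG content accounts for much of the difference in number: 28.5% of X-linked and 52.28% of autosomal genes were CpG-rich, and with autosomal shares in each class 50.6% of X-linked genes would have a peak, against 48.8% observed. The 50.6% lies inside the 95% interval of the X share (45.6% to 52.07%), so the total shows no clear remainder. A small gap remained among CpG-rich genes, where 95.6% of X-linked (258 of 270) and 97.9% of autosomal genes had a peak (two-sided Fisher's exact test, unadjusted p = 0.018). By the limit set beforehand, p under 0.05, this argued against CpG class as the whole cause. Among the 678 other X-linked genes 30.2% did, against 31.8% on the autosomes (Fisher's exact test, p = 0.42). CpG class did not account for the weaker enrichment, whose ratio among CpG-rich genes was 0.627 (95% interval 0.594 to 0.669). Differences in CpG content within a class were not examined. A candidate explanation is that 1 X copy is silent in female cells: 5 genes known to escape X inactivation (Kdm5c 22.6, Kdm6a 19.7, Ddx3x 24.4, Eif2s3x 15.7, Pbdc1 6.09) had a median of 19.7, at percentile 100 of random sets of X-linked genes with a peak, and 14 of 10000 random sets of CpG-rich X-linked genes came as high. Of the 5 genes, 4 lay above the median of X-linked genes with a peak (10.4), and Pbdc1 did not. Fewer X copies in male cells cannot be told apart from a silent copy in female cells. The level these 5 genes would have without any X effect is unknown in 1 tissue. The percentile of 100 had been taken beforehand to go with a silent copy and to argue against fewer copies in male cells. It could arise from a high level of these genes' own, so it decides neither explanation.

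Of the replicated peaks, 6140 (14.6%) were not overlapped by a peak in both replicates' lists, while every pooled peak that was so overlapped was replicated. These peaks were weaker and narrower, with medians of 3.43 and 274 bp against 5.89 and 665 bp. The overlap rule does not explain them, since 5889 remained with 1 bp of overlap. Weak peaks near the calling threshold of the single lists are a candidate explanation. Of the peaks without such overlap, 0% lay in the strongest 20% of the replicated list and 97.7% in its weaker 50%. These shares restate that the peaks were weak, so they cannot decide whether the threshold was the cause. The rule by which a peak was called replicated is not given in the sources used here, and no biological explanation was tested.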
